A study of Mus musculus with 6 samples.

How the data were processed

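The series compares cervical motor neurons of 3 wild-type and 3 Hox5 mutant mouse embryo samples at stage e12.5. Per the labels, the embryos were of mixed C57BL/6, BALB/c and FVB background, the tissue was dissociated with papain and DNase, and motor neurons were collected by fluorescence-activated cell sorting from HB9::GFP embryos. Total RNA was amplified with an Illumina TotalPrep kit and labelled with biotin, per the labels, and each sample was hybridised to 1 single-colour Illumina bead array. Groups and replicate numbers were taken from the sample titles. The labels do not say whether a sample holds 1 embryo or a pool, so p-values measure the spread between these 6 samples.

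The deposited signal table gives, per the file headers, 1 intensity per probe and array on a linear scale and 1 detection p-value per probe and array. The scanner software, any background subtraction on the scanner and the slide of each array are not given in the sources used here. The intensities of this deposited table ran from 71.3 to 56712.5 and their medians differed between arrays, from 97.7 to 109.8. A second deposited table holds values normalized by the authors, intensities on a linear scale with a median between 103.5 and 103.6 on every array. Quantile normalization of the first table without background correction gave the authors' normalized intensities within 1.43% for every probe, which fixes their scale and leaves no centring by gene. The number of columns of per-sample values that matched no sample was 0.

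Background was corrected with limma 3.58.1 in R 4.3.3 by normexp, with the negative control distribution inferred from the detection p-values and an offset of 16, followed by log2 and quantile normalization over all 6 arrays. Probes were kept where the detection p was under 0.05 on at least 3 of the 6 arrays, which left 19735 of 45281. Signal over background on an array sets what can be seen there, and 19307 to 20307 probes per array were detected at that level. Gene symbols came from the platform annotation supplied with the values, in which 34885 probes had 1 symbol, 18 had several and 10378 were unnamed here. Of these, 34807 matched by gene identifier a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names and for chromosomes only. The build behind the array design is not given in the sources used here, so no coordinates are printed. A gene was represented by its probe with the highest mean over all 6 arrays and each unnamed probe stood for itself, giving 13638 features, 10438 of them named.

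Groups were compared with limma's lmFit and eBayes, with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg over all features tested. A feature passed at an adjusted p under 0.05, and differences are mutant minus wild type on the log2 scale. Where a gene was detected on no array of a group, a bound is given as at least N-fold. It sets the mean of the other group against the mean, per array, of the higher of the probe's own value and the lowest value of any detected probe. The 32 gene lists, fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. They covered the Hox5 paralogs, other Hox groups, Hox cofactors, motor neuron identity, motor columns and pools, published phrenic genes, axon guidance, cadherins, immunoglobulin-family adhesion, neurotrophic factors, cell death, retinoids, Notch, Wnt and hedgehog signalling, cytoskeleton, ion channels and synapse. Others held markers of cell division, progenitors, interneurons, sensory neurons, neural crest, mesenchyme, muscle, blood, endothelium and macrophages, and genes of dissociation stress, glycolysis and hypoxia, ribosomal proteins, oxidative phosphorylation and sex. Detected probes and median signals were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1.

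The genes named were set by a rule written before the data were examined. They are the Hox5 genes, the 8 named features with the smallest unadjusted p in each direction where fewer than 5 pass, all published phrenic genes, and the 2 members of each list with the smallest p. For lists called by camera they include the 4 members with the smallest p in the called direction. The test was run on simulated data with the features and spread of these arrays, in which 50 features each were changed 1.5-fold, 2-fold, 4-fold and 8-fold. It recovered 0%, 42%, 90% and 92% of them over all 6 arrays, with 4 false calls. The simulated noise was independent between features and held no shift shared by many features on 1 array.

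The alternatives fixed before the data were examined were no background correction, normexp without detection p-values, an offset of 50, cyclic loess, median scaling, the authors' normalized values, no filter and a stricter filter on dim probes, every probe on its own, an intensity trend with robust variance, array weights, the replicate number as a block, an ordinary t statistic without moderation, other thresholds, each array left out in turn, camera with an estimated correlation, and fry. Sex read from Xist, a score of blood, mesenchyme and endothelium genes as a covariate, and leaving out both arrays numbered 1 were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.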

Results

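Gene expression was measured in motor neurons sorted from the cervical spinal cord of mouse embryos at stage e12.5, when spinal motor neurons are extending their axons. The cells carried the HB9::GFP reporter, which makes motor neurons fluorescent so that a cell sorter can collect them. RNA from 3 wild-type samples and 3 samples labelled Hox5 mutant was hybridised to 1 Illumina bead array each. The mutant genotype, per the labels, combines a conditional Hoxa5 allele recombined by Olig2-Cre, which acts in motor neuron progenitors, with a germline null allele of Hoxc5. Hoxa5 and Hoxc5 are transcription factors of the Hox5 paralog group, which acts at cervical levels of the spinal cord, including the phrenic motor neurons that drive the diaphragm. Each array gave 1 brightness value for each of 45281 probes, and between 19307 and 20307 probes per array were detected above background. The number of arrays limits the precision of every difference below.

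The first comparison concerns the targeted genes themselves. Hoxa5 had a log2 intensity of 13.99 ± 0.0432 (SD, n = 3) on the wild-type arrays and 13.54 ± 0.348 (SD, n = 3) on the arrays labelled mutant. It was detected on every array labelled mutant, with values of 13.15, 13.81 and 13.67 for replicates 1, 2 and 3. Hoxc5 was higher, not lower, on the arrays labelled mutant, at 7.31 ± 0.633 (SD, n = 3) against 6.58 ± 0.105 (SD, n = 3) on the wild-type arrays. Mutant replicates 2 and 3 stood at 7.65 and 7.71, and mutant replicate 1 at 6.58, inside the wild-type range. Hoxb5, the paralog that was not targeted, measured 13.02 ± 0.313 (SD, n = 3) and 12.73 ± 0.342 (SD, n = 3). The difference, mutant minus wild type, was −0.45 on the log2 scale for Hoxa5 (95% confidence interval −0.924 to 0.032), −0.29 for Hoxb5 (−0.862 to 0.274) and 0.73 for Hoxc5 (0.0115 to 1.46). None of the 3 passed, each with a limma adjusted p of 0.998. Without mutant replicate 1 the Hoxa5 difference was −0.24 and the Hoxc5 difference 1.10, with limma adjusted p of 1 and 0.711, and Hoxb5 was at −0.15. Each gene had 1 probe, and whether these probes lie inside the deleted parts is not given in the sources used here, so the values neither check nor contradict the labels with certainty. Because these probes could not check the genotype, the second group is called the arrays labelled mutant throughout. A mutant replicate is an array so labelled, and every direction below rests on that label.

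**Figure D1:**
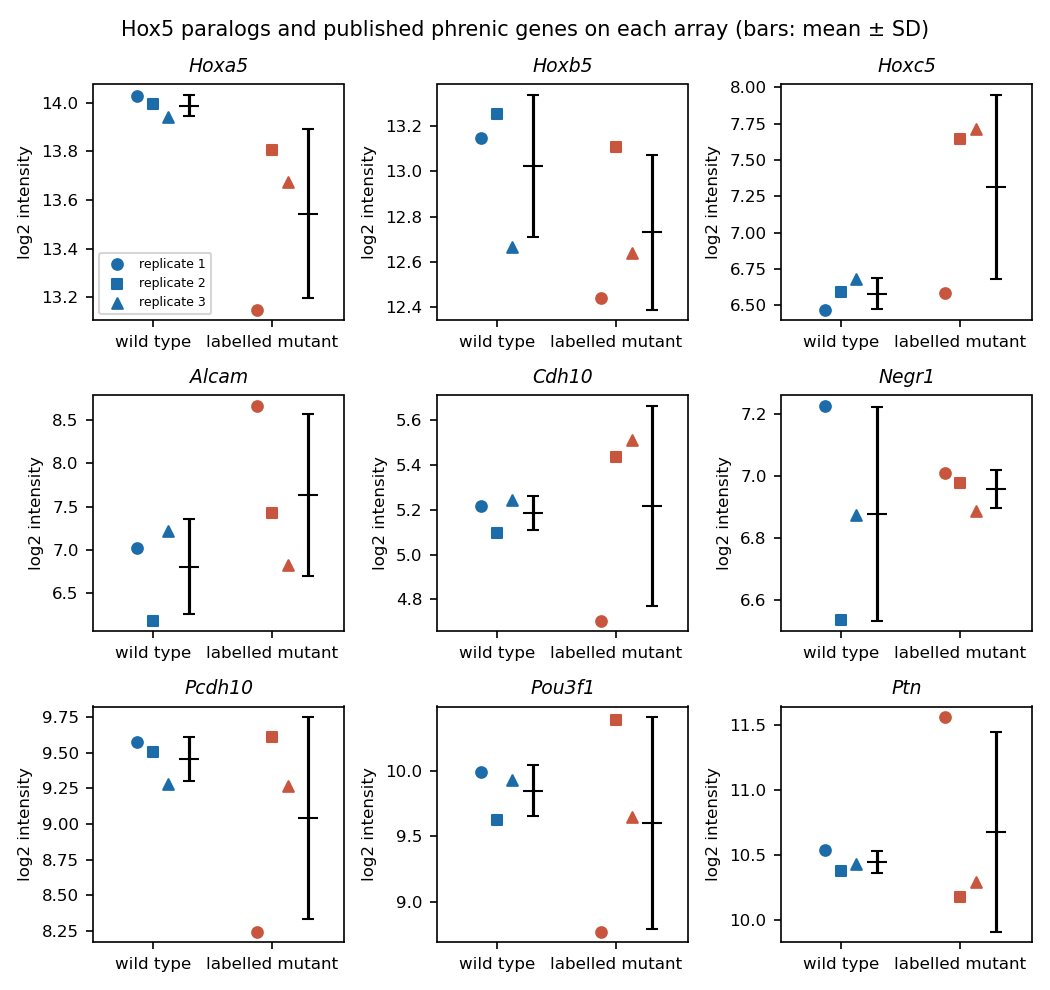
Log2 intensity (vertical axis) of the 3 Hox5 paralogs and 6 published phrenic motor neuron genes on each of 3 wild-type arrays and 3 arrays labelled Hox5 mutant, with the mean and SD of each group as a horizontal mark and bar. Hoxa5 spans 13.15 to 13.81 on the arrays labelled mutant against 13.94 to 14.03 on the wild-type arrays. Mutant replicate 1 lies apart from replicates 2 and 3 for Alcam, Cdh10, Hoxa5, Hoxc5, Pcdh10, Pou3f1 and Ptn.

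The second comparison asks which genes depend on Hoxa5 and Hoxc5 in cervical motor neurons. No gene passed. Among the 16 genes with the smallest unadjusted p, the smallest was that of the THAP domain gene Thap4, at 8.43 ± 0.198 (SD, n = 3) on the arrays labelled mutant against 6.14 ± 0.325 (SD, n = 3) on the wild-type arrays. Prdm13, a transcription factor of dorsal neural tube development, was at 4.98 ± 0.155 (SD, n = 3) against 6.36 ± 0.347 (SD, n = 3), and was detected on 2 of the 3 arrays labelled mutant. Of 13638 features tested with limma, 0 reached an adjusted p of 0.05, and the smallest adjusted p, that of Thap4, was 0.145. An unadjusted p under 0.05 was reached by 241 features, 113 higher and 128 lower on the arrays labelled mutant, where 681.9 would be expected by chance. The 3 values of each group did not overlap for 751 features, or 5.51%, where chance gives 10%. Without mutant replicate 1, 0 features passed, 306 had an unadjusted p under 0.05 and the smallest limma adjusted p was 0.149. Data were also simulated with the spread of these arrays and noise independent between features. There the same test recovered 0% of features changed 1.5-fold, 42% of those changed 2-fold and 90% of those changed 4-fold. The simulation held no shift shared by many features on 1 array, so these shares do not carry over to the real arrays. Thap4, at a 4.89-fold difference, did not pass.

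None of the 8 named genes with the smallest unadjusted p in the higher direction passed. Their differences were 2.29 for Thap4 (95% interval 1.79 to 2.79), 1.65 for Gin1 and 1.61 for Zcchc3, followed by 0.78 for Ppan, a gene of ribosome biogenesis, and 0.78 for Khk, which encodes ketohexokinase. The purine synthesis enzyme gene Atic was at 0.63. Bak1, a pro-apoptotic member of the Bcl2 family, and the defensin gene Defb5 were detected on none of the wild-type arrays and on all 3 arrays labelled mutant, so their signals were at least 1.33-fold and at least 1.14-fold higher there. In the lower direction the differences were −1.37 for Prdm13 (95% interval −1.87 to −0.873), −1.28 for the urotensin gene Uts2b and −1.21 for Maml3, a Notch coactivator. Syndig1l was at −0.86 and Llph at −0.62. The autophagy gene Atg4c, the transcription factor gene Mafa and Fst, which encodes the activin antagonist follistatin, were detected on none of the arrays labelled mutant and on all 3 wild-type arrays, so they were at least 1.39-fold, at least 1.33-fold and at least 1.3-fold lower. The limma adjusted p was 0.998 for each of these genes except Thap4. Another kept probe existed for 7 of the 16 genes, and 4 of those 9 other probes gave the same sign. Those of the same sign were at 0.72 and 1.52 for Zcchc3, 0.55 for Khk and 0.20 for Atic. Opposite to the brighter probe were those of Gin1 at −0.21, Ppan at −0.30, Syndig1l at 0.11 and Llph at 0.068, and another of Atic at −0.029.

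**Figure D2:**
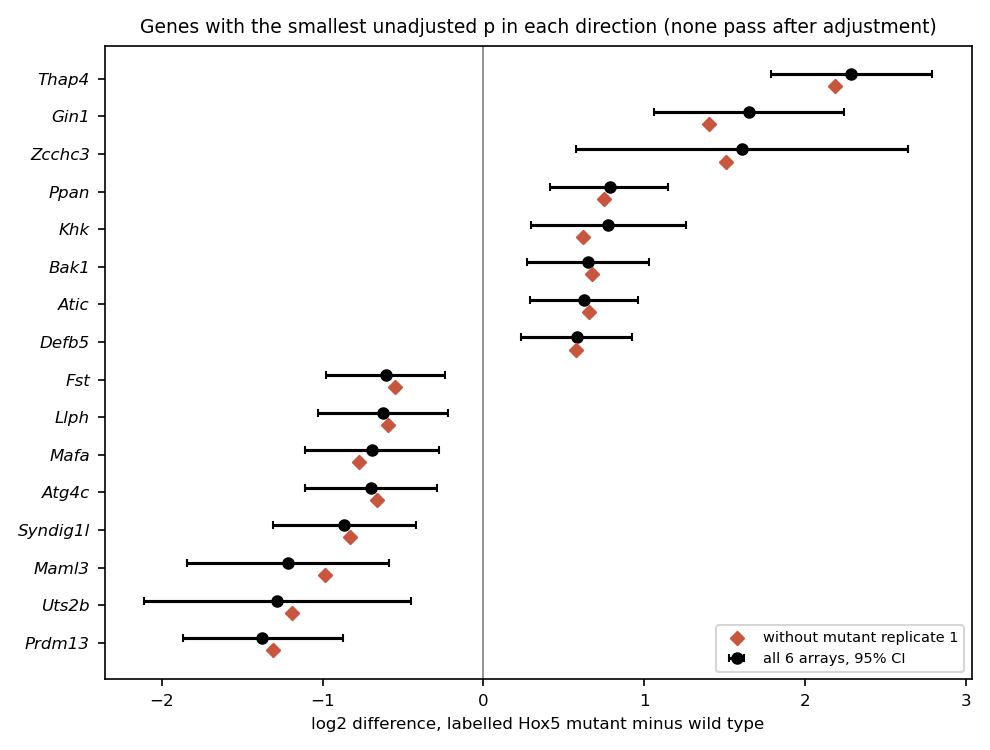
Log2 difference, arrays labelled Hox5 mutant minus wild type (horizontal axis), for the 8 named genes with the smallest unadjusted p in each direction, with 95% confidence intervals over all 6 arrays (circles) and the value without mutant replicate 1 (diamonds). Among the genes shown Thap4 has the largest difference, 2.29 over all 6 arrays and 2.19 without that array, and none of them passes after adjustment. Bak1, Defb5, Atg4c, Mafa and Fst are drawn at their fitted differences and have only bounds.

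The third comparison concerns genes that publications link to Hox5 function in phrenic motor neurons, recalled before the data were examined. None of the 6 that are not Hox5 genes passed. The samples held sorted cervical motor neurons, not phrenic motor neurons alone, so a change confined to phrenic cells could be missed. Alcam, a cell adhesion gene of the immunoglobulin family, was at 7.64 ± 0.935 (SD, n = 3) on the arrays labelled mutant and 6.81 ± 0.549 (SD, n = 3) on the wild-type arrays, a difference of 0.83 (95% interval −0.309 to 1.97). The secreted growth factor gene Ptn differed by 0.23 (−0.613 to 1.07), the POU factor gene Pou3f1 by −0.25 (−1.15 to 0.65) and the protocadherin gene Pcdh10 by −0.41 (−1.21 to 0.386). Negr1 differed by 0.08 (−0.398 to 0.559) and Cdh10 by 0.03 (−0.526 to 0.589). Without mutant replicate 1 the differences were 0.32 for Alcam, −0.016 for Pcdh10 and 0.29 for Cdh10, and the sign turned for Pou3f1, to 0.17, and for Ptn, to −0.21. Of the 8 members, the Hox5 genes included, 0 passed when adjusted over the list alone and 0 over all genes tested, and limma's camera gave the list an adjusted p of 0.699. Some of these genes may have been chosen in publications on these same arrays, so the list is not independent evidence of a direction.

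Lists of genes fixed before the data were examined were then compared with all other genes by camera, and 5 of 32 passed with a preset correlation. The lists of blood, mesenchyme and endothelium genes passed in the higher direction, and those of motor neuron identity and interneurons in the lower direction, while no single member passed. With a correlation estimated per list none of the 5 held, and the unadjusted p was 0.196 for blood, 0.31 for mesenchyme, 0.342 for endothelium, 0.291 for motor neuron identity and 0.367 for interneurons. All 8 blood genes tested were higher, with a median difference of 1.13 and a camera adjusted p of 0.00961. Blood examples were the globin genes Hbb-bh1 at 1.77, Hba-a1 at 1.73 and Hbb-b2 at 0.98. The haem synthesis gene Fech was detected on none of the wild-type arrays and on all 3 arrays labelled mutant, at least 1.05-fold higher there. All 9 mesenchyme genes were higher, by a median of 0.71 (camera adjusted p 0.0174), among them Lgals1 at 1.30, Fbln1 at 1.07, Twist1 at 0.71 and Fstl1 at 0.70. Of 10 endothelium genes 9 were higher, by a median of 0.81 (camera adjusted p 0.0174), with the tight junction gene Cldn5 at 1.26, Esam at 1.09, Ets1 at 1.08 and Igfbp7 at 1.06. Mutant replicate 1 was the highest of the 6 arrays for 26 of the 27 genes of these 3 lists, and its median relative to the other 5 was 3.62 for blood, 2.61 for mesenchyme and 2.59 for endothelium. Mutant replicates 2 and 3 stood at −0.24 and 0.01 relative to the wild-type mean for blood, 0.14 and −0.47 for mesenchyme, and −0.039 and −0.40 for endothelium. Without that array none of the 3 lists passed, with a median of −0.04 and a camera adjusted p of 0.904 for blood, −0.25 and 0.0528 for mesenchyme, and −0.22 and 0.0528 for endothelium. In the same comparison Hbb-bh1 was at 0.41, Hba-a1 at 0.0024, Lgals1 at −0.25, Fbln1 at −0.16, Twist1 at 0.087 and Fstl1 at 0.10. Cldn5 was at −0.15, Esam at 0.25, Ets1 at 0.020 and Igfbp7 at −0.17. Hbb-b2 was detected on neither mutant replicate 2 nor 3, so its fitted difference of 0.011 is not a measured size. Without wild-type replicate 3 the camera adjusted p was 0.0986 for blood, 0.0986 for mesenchyme and 0.0872 for endothelium, and without wild-type replicate 1 it was 0.0601 for endothelium, so these calls were lost as well. In the latter fit mesenchyme was only just under the threshold, at 0.05 when rounded.

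Of 15 motor neuron identity genes 13 were lower, by a median of −0.27 (camera adjusted p 0.022), and with an estimated correlation the p was 0.291. The LIM homeobox genes Lhx4, Lhx3 and Isl1 were at −1.43, −0.66 and −0.36, and Chat, which encodes the enzyme that makes acetylcholine, was at −0.38. Of 21 interneuron genes 18 were lower, by a median of −0.27 (camera adjusted p 0.0283, and p 0.367 with an estimated correlation), with Dmrt3 at −0.72, Pax2 at −0.50, Barhl1 at −0.40 and Prdm8 at −0.39. Mutant replicate 1 was the lowest array for 9 of these 15 and 15 of these 21 genes, with a median relative to the other 5 of −0.72 and −0.69, beside 3.62 for blood on the same array. Without it the medians were −0.06 for motor neuron identity and 0.03 for interneurons, both lists had a camera adjusted p of 0.692, and Lhx4 was at −0.16, Lhx3 at −0.31, Dmrt3 at −0.31, Pax2 at −0.095 and Barhl1 at −0.057. Motor neuron identity genes stood at 0.27 on mutant replicate 2 and −0.48 on mutant replicate 3, and interneuron genes at 0.09 and 0.02, relative to the wild-type mean. The motor neuron identity call was also lost without wild-type replicate 1 (camera adjusted p 0.111), wild-type replicate 3 (0.139) or mutant replicate 3 (0.31), and the interneuron call without wild-type replicate 1 (0.0898) or 3 (0.0986). No member of the 5 lists passed, over all genes tested or adjusted over the list alone. At an estimated correlation 0 of the 32 lists passed, and fry, which tests each list without reference to other genes, called 0 for direction and 0 for change in either direction.

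**Figure D3:**
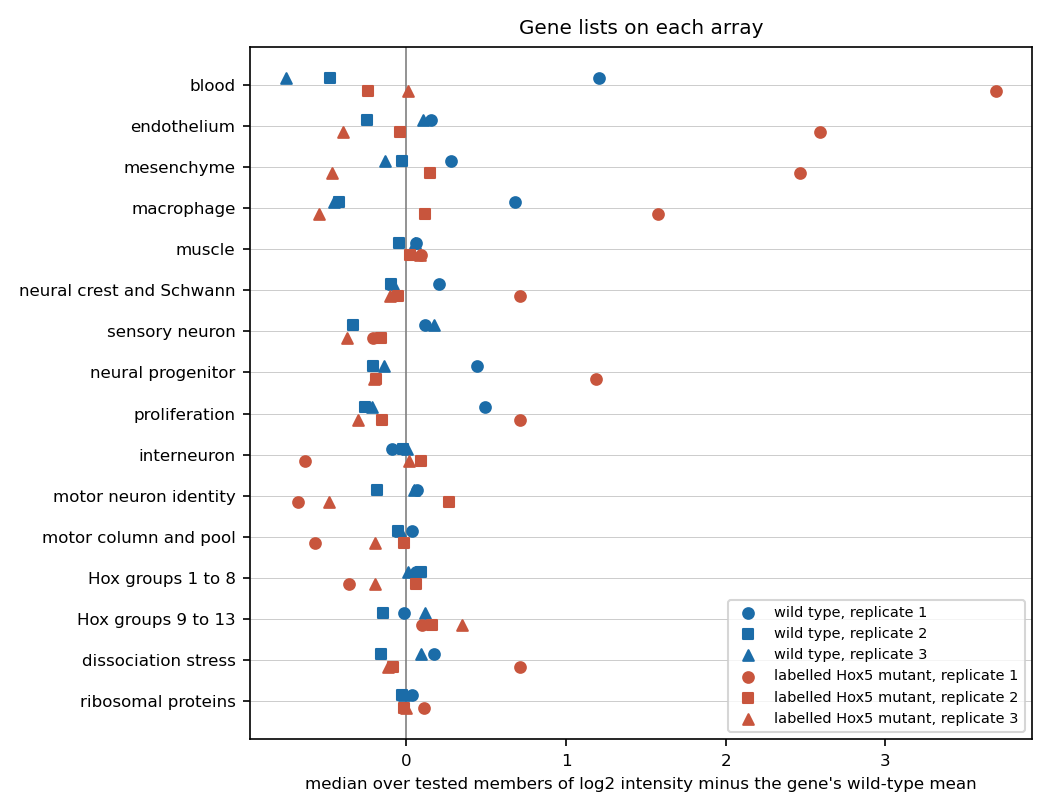
Median over the tested members of a gene list of the log2 intensity minus the gene's wild-type mean (horizontal axis), for 16 lists on each of 3 wild-type arrays and 3 arrays labelled Hox5 mutant, marked by replicate number. Mutant replicate 1 lies at 3.70 for blood, 2.59 for endothelium and 2.47 for mesenchyme, and wild-type replicate 1 is the next highest for blood, at 1.20.

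When mutant replicate 1 was left out, 1 of the alternatives planned for every array, 4 other lists passed, all lower on the arrays labelled mutant. Cell division genes were lower for 19 of 23 members (camera adjusted p 0.000526, and p 0.263 with an estimated correlation), and Notch, Wnt and hedgehog genes for 22 of 26 (0.000526, and p 0.228 with an estimated correlation). Neural progenitor genes were lower for 17 of 18 (0.00743, and p 0.28 with an estimated correlation), and neurotrophic factors and receptors for 13 of 16 (0.0324, and p 0.054 with an estimated correlation). Over all 6 arrays none of the 4 passed. With other arrays left out, 2 of the 4 passed in the opposite direction: Notch, Wnt and hedgehog genes as higher without mutant replicate 2 (0.0238, and p 0.484 with an estimated correlation) or 3 (0.0289, and p 0.442 with an estimated correlation), and cell division genes as higher without wild-type replicate 1 (0.0289, and p 0.444 with an estimated correlation). Wild-type replicate 1 was the highest wild-type array for progenitor genes, at 0.44 relative to the wild-type mean against −0.21 and −0.14 for replicates 2 and 3. With both arrays numbered 1 left out, none of these 4 lists passed and the blood list alone did, with 6 of 8 genes higher on the arrays labelled mutant (camera adjusted p 0.00096, and p 0.118 with an estimated correlation).

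Among Hox genes, 13 of 17 members of paralog groups 1 to 8 were lower on the arrays labelled mutant, by a median of −0.19, and the list did not pass (camera adjusted p 0.0523). It passed under 10 of the 21 other choices of processing, test or arrays that were fixed before the data were examined, with adjusted p from 0.00366 to 0.0482, and with an estimated correlation the p in those 10 fits ran from 0.122 to 0.335. Hoxc6 was at −0.53 and Hoxa2 at −0.44. In 12 of the 17 the lowest array was mutant replicate 1, and without it the median was −0.06, the camera adjusted p 0.785 and Hoxa2 at −0.15. Of 6 genes of paralog groups 9 to 13, which act at thoracic to sacral levels, 4 were higher (median 0.16, camera adjusted p 0.275). Hoxd11 was at 0.45 and Hoxa13 at 0.32, with the other kept probe of Hoxa13 at −0.23. Hoxd11 was detected on 1 wild-type array and 2 arrays labelled mutant, so the size of its difference is uncertain. The 3 Hox5 paralogs as a list had a camera adjusted p of 0.699. Of 8 Hox cofactor genes 6 were lower (median −0.14, adjusted p 0.416), with Meis2 at −0.44 and Meis1 at −0.23. Motor column and pool genes were lower for 13 of 19 (median −0.23, adjusted p 0.434), and within them Lhx3 was at −0.66 and Nos1, which encodes neuronal nitric oxide synthase, at 0.49. Retinoid signalling genes gave 4 of 7 higher (median 0.13, adjusted p 0.699), with Crabp2 at −0.31 and Rxrg at 0.37. The cofactors split evenly when mutant replicate 1 was left out, 4 higher and 4 lower (median 0.02), and 4 of 7 retinoid genes were lower (median −0.046). Motor column and pool genes were then still lower for 13 of 19, with a median of −0.064 (camera adjusted p 0.785). The values were then −0.12 for Meis2, −0.12 for Meis1, −0.31 for Lhx3, −0.074 for Crabp2 and −0.046 for Rxrg.

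No list of genes that shape axons and their contacts passed. Of 50 axon guidance genes 26 were higher (median 0.03, camera adjusted p 0.699), with Sema4g at −0.40 and Sema3b at 0.49. Of 21 cadherins and protocadherins 13 were lower (median −0.11, adjusted p 0.416), and Cdh2, which encodes N-cadherin, had the smallest unadjusted p among them with a difference of −1.22 (95% interval −2.15 to −0.296). Cdh2 was detected on all 3 wild-type arrays and 1 array labelled mutant, and Pcdh20 was at −0.56. Of 30 immunoglobulin-family adhesion genes 16 were lower (median −0.01, adjusted p 0.699), with Cntn2 at 0.60 and Cntn3 at 0.41. Neurotrophic factors and receptors split evenly, 8 higher and 8 lower (median −0.02, adjusted p 0.416), with Gfra4 at −0.48 and Bdnf at −0.35. Neuronal cytoskeleton and growth genes were lower for 22 of 27 (median −0.10, adjusted p 0.186), with Map2 at −0.29 and Ina at −0.19. Mutant replicate 1 was the lowest array for 21 of these 27. Synapse genes were lower for 27 of 46 (median −0.04, adjusted p 0.971), with Syp at −0.30 and Syt13 at 0.45, and ion channel genes for 21 of 35 (median −0.06, adjusted p 0.992), with Kcnf1 at −0.57 and Kcnk1 at 0.53. Cell death genes were lower for 13 of 24 (median −0.02, adjusted p 0.699), with Bak1 at least 1.33-fold higher and Sesn2 at −0.32. The tally turned for 3 of these lists when mutant replicate 1 was left out, with 19 of 27 cytoskeleton genes higher (median 0.04), 30 of 46 synapse genes (median 0.06) and 25 of 35 ion channel genes (median 0.07), and axon guidance genes split evenly, 25 and 25. Cadherins and protocadherins were then lower for 12 of 21, with a median of −0.013. The values were then −0.22 for Sema4g, 0.15 for Sema3b, −0.23 for Pcdh20, −0.17 for Map2, 0.31 for Kcnk1 and −0.14 for Sesn2. The other kept probe of Kcnk1 was at −0.0027 over all 6 arrays.

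Markers of other cells and of sample quality were read from the same arrays. Neural progenitor genes were higher for 13 of 18 (median 0.22, camera adjusted p 0.493), with Neurog2 at −0.57 and Nkx2-2 at −0.32, and cell division genes for 14 of 23 (median 0.03, adjusted p 0.699), with Pcna at −0.52 and Mcm6 at 0.33. Notch, Wnt and hedgehog genes were higher for 19 of 26 (median 0.15, adjusted p 0.416), with Dll1 at −0.40 and Jag1 at −0.29. On mutant replicate 1 the median relative to the other 5 arrays was 1.32 for progenitor genes and 0.86 for cell division genes. Neural crest and Schwann genes were higher for 7 of 10 (median 0.16, adjusted p 0.699), with Tfap2b at −0.33 and Foxd3 at 0.21. All 4 sensory neuron genes were lower (median −0.25, adjusted p 0.178), with Pou4f1 at −0.39 and P2rx3 at −0.26, and all 3 macrophage genes were higher (median 0.49, adjusted p 0.239), with Cx3cr1 at 0.49 and Laptm5 at 0.81. Muscle genes were lower for 5 of 8 (median −0.07, adjusted p 0.988), with Tnnt1 at 0.47 and Myl4 at 0.33. Stress genes that respond to tissue dissociation were higher for 15 of 23 (median 0.11, adjusted p 0.416), with Ier3 at 0.74 and Hsph1 at 0.30. Genes of glycolysis and hypoxia gave 13 of 22 higher (median 0.01, adjusted p 0.992), with Higd1a at −0.42 and Pkm at 0.35. Ribosomal protein genes gave 35 of 53 higher (median 0.04, adjusted p 0.129), with Rpl22l1 at 0.45 and Rpl31 at 0.22, and genes of oxidative phosphorylation 51 of 82 (median 0.03, adjusted p 0.416), with Ndufb2 at 0.33 and Ndufaf2 at 0.28. For most of these lists the tally turned when mutant replicate 1 was left out. Lower were then 17 of 18 progenitor genes, 19 of 23 cell division genes, 22 of 26 Notch, Wnt and hedgehog genes, 8 of 10 neural crest and Schwann genes (median −0.17), 2 of 3 macrophage genes (median −0.26), 16 of 23 dissociation stress genes (median −0.10), 17 of 22 glycolysis and hypoxia genes (median −0.083), 27 of 53 ribosomal protein genes and 43 of 82 genes of oxidative phosphorylation. Of the genes named, Neurog2 was then at −0.14, Mcm6 at 0.045, Dll1 at −0.15, Tfap2b at −0.063, Pou4f1 at −0.076 and P2rx3 at −0.17. Cx3cr1 was then at 0.12, Laptm5 at −0.26, Tnnt1 at 0.21, Myl4 at −0.0085 and Ier3 at 0.36. Pcna was detected on neither mutant replicate 2 nor 3, so its fitted difference of −0.83 is not a measured size. On mutant replicate 1 the median relative to the other 5 was 1.71 for macrophage, 0.78 for neural crest and Schwann and 0.61 for dissociation stress genes. Median, mean and test differed in sign for 3 lists, those of cell death, immunoglobulin-family adhesion and muscle. For some genes of this paragraph another kept probe differed over all 6 arrays. The other probes of Mcm6 were at 2.59 and 0.32, that of Nkx2-2 at 0.039 and that of Pkm at −0.37.

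Sex-linked genes differed within both groups. Xist, which is expressed from the inactive X chromosome of females, was at 11.68 on wild-type replicate 1 and at 11.52 and 11.78 on mutant replicates 1 and 2, and between 4.45 and 4.92 on the other 3 arrays. The Y-linked genes Eif2s3y and Kdm5d were detected on those other 3 arrays, with differences between the groups of −1.66 and −0.90 (−0.88 and −0.53 without mutant replicate 1), and the sex-linked list had a camera adjusted p of 0.699. The number of detected probes was 19683 ± 544 (SD, n = 3) on the wild-type arrays and 19678 ± 309 (SD, n = 3) on the arrays labelled mutant, with a two-sided exact permutation p of 1. The median signal was 100.57 ± 2.53 (SD, n = 3) against 106.53 ± 3 (SD, n = 3), with an exact permutation p of 0.1, the smallest that 3 arrays against 3 can give. The mean correlation of an array with the other 5, over kept probes, was 0.951 for mutant replicate 1 and between 0.974 and 0.979 for the rest, genes not being independent replicates.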

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

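The covariates for sex and for the other-cell score (the mean of blood, mesenchyme and endothelium genes), the fit with both arrays numbered 1 left out and the counts of detected probes with each array left out were chosen after the results were seen; the other alternatives were planned. The count of genes past the threshold was 0 and stayed 0 in all alternatives run except median scaling, with 1 (Thap4, limma adjusted p 0.0282), and the fit without mutant replicate 3. Leaving out each array in turn gave 0 to 1 genes, the 1 being Cops8, named here after its values were seen, at a log2 difference of 5.16 and a limma adjusted p of 0.000666. The number of features with an unadjusted p under 0.05 ran from 131 to 849. Thap4 stayed higher on the arrays labelled mutant in every alternative, by 1.498 to 2.479, with adjusted p from 0.0282 to 0.99. Hoxa5, Hoxb5 and Hoxc5 kept their direction and passed in none of the alternatives, with differences of −0.58 to −0.22, −0.49 to −0.016 and 0.47 to 1.10. The difference in detected probes, −4.33, kept within 1 SD when the detection threshold was stricter (−111) or an array was left out. The cause of these shifts was not tested.

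The count of lists past the threshold was 5. It became 8 with every probe on its own, 0 with array weights, 1 with sex as a covariate (motor neuron identity, camera adjusted p 0.0114, and p 0.239 with an estimated correlation), 1 with both arrays numbered 1 left out, 0 by camera with the correlation estimated per list, and 0 by fry for direction and 0 for mixed change. Leaving out each array in turn gave 0 to 9 lists: 3 without wild-type replicate 1, 0 without wild-type replicate 3 and 9 without mutant replicate 2. Array weights gave mutant replicate 1 a weight of 0.271, against 0.868 to 2.22 for the others. With the other-cell score as a covariate, 4 lists passed. Sensory neuron genes, lower before, passed as lower (camera adjusted p 0.0318, and p 0.0662 with an estimated correlation). Passing as lower were also 3 lists that were higher before, Notch, Wnt and hedgehog (camera adjusted p 0.000796, and p 0.139 with an estimated correlation), cell division (9.14e-05, and p 0.193 with an estimated correlation) and progenitors (0.0111, and p 0.233 with an estimated correlation). The called lists of mesenchyme (camera adjusted p 0.817) and endothelium (0.844) turned lower without passing, and the blood call was lost (0.844). The score is the mean of the genes of these 3 lists. The fit thus takes out their shared shift by construction, and the loss of their calls tests nothing. With both arrays numbered 1 left out, interneuron genes turned higher (0.998) and mesenchyme (0.788) and endothelium (0.391) lower, without passing. Leaving out each array in turn, the camera adjusted p ran from 0.000526 to 0.95 for Notch, Wnt and hedgehog, 0.000526 to 0.799 for cell division, 0.00743 to 0.984 for progenitors, 0.000277 to 0.692 for interneurons, 7.94e-05 to 0.0986 for mesenchyme, 0.000254 to 0.904 for blood and 0.000101 to 0.0872 for endothelium. Each of these 7 turned direction without mutant replicate 1. For motor neuron identity it ran from 1.74e-07 to 0.692, always as lower, with the call lost in 4 of the 6 fits and an unadjusted p of 0.0258 with an estimated correlation in the fit without mutant replicate 2.

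Of the 93 named genes, 17 changed sign in at least 1 alternative, and none of these passed in any. With array weights Pou3f1 was at 0.19 and Ptn at −0.12. With sex as a covariate Kdm5d was at 0.0040 and Negr1 at −0.024, and with the other-cell score Laptm5 was at −0.11, Pou3f1 at 0.060 and Ptn at −0.13. With both arrays numbered 1 left out the values were −0.051 for Tnnt1, 0.027 for Lhx4, −0.070 for Mcm6, 0.046 for Pcdh10, 0.10 for Tfap2b, −0.0033 for Fbln1, −0.39 for Lgals1, −0.26 for Igfbp7, −0.019 for Myl4, 0.24 for Pou3f1 and −0.17 for Ptn. Over the fits that left out each array in turn, the ranges were −0.15 to 2.11 for Cldn5, −0.16 to 1.84 for Fbln1, −0.25 to 2.27 for Lgals1, −0.17 to 1.84 for Igfbp7, −0.046 to 0.65 for Rxrg, −0.0085 to 0.64 for Myl4, −0.26 to 1.49 for Laptm5, −0.64 to 0.17 for Pou3f1, −0.21 to 0.47 for Ptn, −0.091 to 0.25 for Negr1 and −0.11 to 0.29 for Cdh10. Without mutant replicate 1, 9 of the 93 turned sign and 39 kept it but moved by more than 1.5 times. The stricter filter left 59 of the 93.

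Lists that had not passed did so in some alternatives by camera with the preset correlation: Hox groups 1 to 8 as lower in 10 of 24 (adjusted p 0.00366 to 0.0482, and p 0.122 to 0.335 with an estimated correlation in the same fits), ribosomal proteins as higher in 5 of 24 (0.0179 to 0.0407, and p 0.265 to 0.341 with an estimated correlation), macrophages as higher in 3 of 23 (0.0182 to 0.0409, and p 0.171 to 0.31 with an estimated correlation), neuronal cytoskeleton as lower in 2 of 24 (0.00299 to 0.00492, and p 0.263 to 0.444 with an estimated correlation) and sensory neurons as lower in 2 of 23 (0.0178 to 0.0318, and p 0.0497 to 0.0662 with an estimated correlation). With the replicate number as a replicate block, 0 genes and 7 lists passed, Hox groups 1 to 8 and macrophages among them (camera adjusted p 0.0409 each, and p 0.335 and 0.232 with an estimated correlation). The samples share only a number: deviations from the group means correlated across probes by 0.325, 0.0229 and 0.136 for the pairs numbered 1, 2 and 3, and wild-type replicate 2 correlated more with mutant replicate 3, at 0.391. A slide block was not run, since the slide of each array is not given in the sources used here. Low signal over background leaves genes such as Bak1, Defb5, Atg4c, Mafa and Fst with bounds only.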

Other observations

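The tests of explanations below, the splits of the arrays among them, were chosen after the results were seen.

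The sorted samples carried transcripts of several cell classes on every array, wild type included. Interneuron genes were detected on all 6 arrays for 17 of 28, progenitor genes for 17 of 23, blood genes for 5 of 13, mesenchyme genes for 8 of 26 and endothelium genes for 7 of 21. Of the 27 blood, mesenchyme and endothelium genes tested, 20 were detected on all 6 arrays. Wild-type replicate 1 had the highest wild-type median for blood, mesenchyme, progenitor and cell division genes, all of which were also highest on mutant replicate 1. The embryonic globin gene Hbb-y was at 12.33 on wild-type replicate 1 and 14.96 on mutant replicate 1, and between 9.55 and 10.53 on the other 4 arrays. Vim, which encodes an intermediate filament of progenitors and connective tissue, was at 10.76 and 11.20 on those 2 arrays and between 9.18 and 9.95 on the rest. These genes were picked after their values were seen.

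Mutant replicate 1 stood apart from the other 5 arrays on the first principal component, which held 56.3% of the variance. A lower share of motor neurons alone would raise the markers of every other class, yet the interneuron median on that array was −0.69 relative to the other 5, with 19 of 21 genes below. Loss of the Hox5 genes would raise blood, mesenchyme and endothelium genes on mutant replicates 2 and 3 as well, but their medians there, −0.0606 and −0.316, lay within or below the wild-type arrays' −0.161 to 0.279. Weak hybridisation of that array was not settled: its number of detected probes, 20011, lay inside the range of 19307 to 20307 of the others, but at the stricter detection threshold its 16352 was the lowest, against 16397 to 17070. RNA of blood and connective tissue cells that escaped the GFP sort is a candidate explanation, since 26 of the 27 marker genes were highest on that array, with Hba-a1 at 15.05, Lgals1 at 11.05 and Sparc at 11.59.

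Hoxc5 signal was higher on mutant replicates 2 and 3 but not on mutant replicate 1. Dilution of motor neuron RNA in replicate 1 may contribute: Hoxc5 stood there at −1.10 relative to the other 2 mutant arrays, and 7 of 32 genes of motor neuron identity and Hox groups 1 to 8 were at least as far below, with a median of −0.48 over the 32. A wrong label for replicate 1 was not settled either. Of 6 features chosen by a small unadjusted p on the other 5 arrays, 3 lay nearer to mutant replicates 2 and 3 on that array, Thap4, Gin1 and Prdm13. The rest lay nearer to the wild type, but Hoxc5 was 1 of these (unadjusted limma p 0.000209 without that array). Since Hoxc5 is the pattern to be explained, it adds no support for a wrong label. Too few features separate the other arrays to decide. Whether the mutation itself raises signal from the Hoxc5 probe, for instance from a part of the transcript that is left, was not tested, since the probe's place is not given in the sources used here.

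Thap4, Gin1 and Atic, 3 of the 16 genes with the smallest unadjusted p, lie on chromosome 1. The rise of Gin1 and Atic was that of their brightest probe. The other kept probe of Gin1 was at −0.21, those of Atic were at 0.20 and −0.029, and Thap4 had no other kept probe. Their differences without mutant replicate 1 stayed at 0.66 or more. The groups did not overlap for any of the 3 genes over all 6 arrays, so their direction had to hold without that array. The fit without it therefore does not test cells of other types in mutant replicate 1. DNA carried along with the targeted loci does not account for these genes, since 0 of the 3 lie on the chromosomes of Hoxa5 or Hoxc5, 6 and 15. Strain DNA around these genes, which may differ between embryos of a mixed background, could not be decided. With the 3 genes, chromosome 1 held 20 features at an unadjusted p under 0.05 where 8.95 were expected (one-sided Fisher's exact p 0.0122 after adjustment over 20 chromosomes). Without the 3 genes, it held 17 where 8.75 were expected, with a one-sided Fisher's exact p of 0.00656, or 0.131 after that adjustment. Chromosome 1 was picked after the results were seen. The test covered all of it, so a shorter stretch around the genes was not tested. With no gene left out, some chromosome passed in 3 of the 10 splits of the arrays, the real split included, and an effect of the genotype stays open as untested.

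With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes, a count that each of the 10 splits reaches of necessity, so for genes the comparison shows nothing; the highest of the other splits gave 6. The real split gave 5 lists, 8 of 10 splits gave as many, and the highest other split gave 15. The split that sets wild-type replicate 1 and mutant replicates 1 and 2 against the rest, which is also the split by Xist, called 6 genes and 2011 features at an unadjusted p under 0.05 against 241 for the real split, which points to a structure of the samples other than genotype. The same 3 arrays also had the highest other-cell scores, 7.361, 9.816 and 6.869 against 6.653 to 6.733 on the rest. Mutant replicate 2, at 6.869, lay close to the rest. This split thus follows sex and, for both arrays numbered 1, RNA of other cells. With sex as a covariate, limma called 0 genes at an adjusted p under 0.05 and 194 features at an unadjusted p under 0.05.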
